A study of Mus musculus with 8 samples.

How the data were processed

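Signals were measured on 8 Affymetrix mouse arrays, 1 sample per array, 4 of confluent and 4 of subconfluent mouse aortic endothelial cells, each from the same number of cells per the labels. The deposited values are signal, 1 linear value per probe set, made by the authors with the Affymetrix statistical algorithm and scaled on each array to a target of 500, per the labels. The software version, the labelling kit batch and the passage of the cells were not given in the sources used here. In the table every array had a mean of 500 to the nearest whole number after the lowest and highest 2% of probe sets were left out, so the values were taken as already scaled, and no further normalization was applied. The scale factors, noise and chip lots of the arrays came from the labels. The table held 1 value column per array, and the image files and detection calls were not used here.

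Of 12488 probe sets 66 were controls and were left out. The array's annotation gave 1 gene symbol for 10855 probe sets, several for 396 and none for 1237, of which 44 were controls. For 10839 the gene identifier was found in the mouse RefSeq gene table, and 0 symbols had to be updated. Probe sets with several or no symbols were tested but not named or put in lists. Positions on the genome were not used here. Probe sets with a mean signal of at least 200 over the 8 arrays were kept, which left 6007, among them 5443 with 1 symbol that stood for 4670 genes. For each gene the probe set with the highest mean signal stood for it. Signals were put on the log2 scale after adding 50, which shrinks the fold of genes with low signal. Fold changes are those of these log2 values, and errors of signals are standard deviations over 4 arrays.

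Subconfluent was compared with confluent by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance with the mean, 6 residual degrees of freedom, no block), as a two-sided test with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The p-values measure the spread between the arrays, and beyond the experiment numbers the labels do not say how the cultures were made. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Shifts of gene lists were tested by limma's camera with a preset correlation of 0.01 between genes, adjusted over 27 lists, and again with an estimated correlation and with limma's fry, which asks whether a list's genes move on balance in 1 direction without setting them against other genes. Of the 27 lists 9 follow categories that the labels name (endothelial markers, endoplasmic reticulum, Golgi, lysosome, peroxisome, DNA replication, mitosis, tubulins and microtubule proteins, kinesins). The other 18 are growth arrest, junctions, extracellular matrix, actin, YAP targets, immediate early genes, interferon, antigen presentation, inflammation, cholesterol, glycolysis, electron transport, ribosomal proteins, ribosome biogenesis, splicing, proteasome, antioxidant genes and Notch. A further 7 lists held markers of smooth muscle cells, fibroblasts and pericytes, macrophages, lymphocytes, red blood cells, adipocytes, and epithelial and mesothelial cells, which were described without a test of their own in the 27. For members of a list the count that passed is given over all probe sets and adjusted over the list alone.

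The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took in each direction the 12 genes with the largest change among those that passed with no overlap between the groups' 4 values, and for each list up to 4 members with the smallest p. Genes named beyond it are marked as such. It gave 137 genes, of which 79 passed, 115 passed with the pairs as a block, and 127 had the same direction in all 4 pairs. In 23 of them the probe set's name marks a sequence shared within a gene family or otherwise not unique. Another tested probe set existed for 27 of them, and in 4 cases it had the opposite sign. These 4 genes are not marked below, and a direction given for them is that of the probe set with the highest mean signal. Their direction thus depends on the probe set chosen.

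Both groups are numbered 1 to 4 as experiments in the labels. To check whether these numbers pair the samples, each array's deviations from its group mean were correlated across probe sets. Arrays of the same number gave correlations of 0.486, 0.357, 0.516 and 0.348, and the highest with another number was 0.0681, so a fit with the pairs as a block was run beside the unpaired fit. Arrays were also compared within chip lots, with the lot as a fixed or random block, within lot A (1 array against 1, no test) and within lot C (1 against 2). Further alternatives were a pseudocount of 1 or 150, no filter or a filter of 500, quantile normalization, median centring, the log2 scale factor as a covariate, array weights, no variance trend, a minimum log2 difference of 1, genes in place of probe sets, the mean of a gene's probe sets, and leaving out each array. Leaving out each pair from the paired fit was added after the data were seen. Correlations of the log2 values were 0.896 to 0.959 within confluent, 0.924 to 0.961 within subconfluent and 0.772 to 0.932 between groups, and 0 pairs of arrays were identical.

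The procedure was tested on simulated data in 10 runs of 6007 probe sets with 200 changed in each. The unpaired and paired fits called 7.31% and 17.8% of changes of 0.5 on the log2 scale, 60.9% and 67.5% of changes of 1, and 95.6% and 94.5% of changes of 2. They called 24 and 47 of 58070 unchanged probe sets. A simulated list shift of 0.5, in a separate single run without pair effects, came back as 0.50. The simulated probe sets were independent of each other, so the runs do not show how often camera calls lists of correlated genes that are not shifted.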

Results

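RNA of cells that the labels name mouse aortic endothelial cells, the cells that line the aorta, was measured on 8 single-colour Affymetrix mouse oligonucleotide arrays. Only 28.9% of endothelial markers reached a mean signal of 200, against 56.6% of all genes and 72.7% of fibroblast and pericyte markers. Whether the RNA came mostly from endothelial cells therefore stays open, as described below. On 4 arrays the RNA came from a mature confluent monolayer. On the other 4 it came from subconfluent cultures at under 50% confluency, with the same number of cells per sample. The comparison asks how gene expression differs between cells that have filled the dish and cells with free space around them. Of 12488 probe sets, 12422 were not controls. The 6007 with a mean signal of at least 200 were tested. The scale factors that brought the arrays to a common level ran from 3.05 to 13.3, and the median signal per array from 169 to 187. The number of arrays limits the precision. In both groups the samples are numbered 1 to 4 as experiments. Arrays with the same number deviated together, so the numbers were taken to pair the samples. The scale factors also ranked alike in both groups, highest on replicate 2 and lowest on replicate 4. What the arrays of a pair share was not tested. The arrays came from 4 chip lots, of which lot A held confluent replicate 1 and subconfluent replicate 1, and lot C held confluent replicate 3 and subconfluent replicates 3 and 4. The remaining lots held arrays of 1 group each, so with chip lot as a fixed block only lots A and C inform the difference between the groups. The first principal component, with 47.1% of the variance, placed the confluent arrays from -39.4 to -4.23 and the subconfluent arrays from 13.7 to 30.3, with confluent replicate 2 nearest to the subconfluent arrays.

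Subconfluent cells carried far more Ccn2 transcript, which encodes a secreted matricellular protein, and far less Saa3 transcript, which encodes an acute-phase protein. Ccn2 had a signal of 388 ± 89.2 in confluent and 5582 ± 2301 in subconfluent cells (SD, n = 4), 12.03-fold higher (limma adjusted p = 0.000534). Saa3 had a signal of 7816 ± 5651 in confluent and 196 ± 268 in subconfluent cells (SD, n = 4), 38.8-fold lower (adjusted p = 0.00362). Next among the higher genes came Hmga2, a chromatin protein of proliferating and embryonic cells, which rose 5.32-fold (log2 2.41 ± 0.25 SE, adjusted p = 0.00105). The phosphate transporter gene Slc20a1 rose 3.20-fold. The hyaluronan receptor gene Cd44 rose 3.11-fold, the kinase genes Plk2 and Epha2 2.90-fold and 2.50-fold, and Ccn1, a relative of Ccn2, 2.63-fold. The other genes with the largest rises, among those without overlap between the groups' values, were Snora7a, Otud4, Fubp1, Nqo1 and Rcc1, between 2.41-fold and 3.99-fold. The probe set of Otud4 can detect related sequences, and the name of that of Nqo1 marks a sequence that may not be unique. Among the lower genes, Mgp, an inhibitor of calcification, fell 11.1-fold (log2 -3.48 ± 0.36 SE, adjusted p = 0.00105). The secreted proteins Hp (haptoglobin), Serpina3n, Apoe and Clu fell between 6.35-fold and 9.50-fold. The growth arrest genes Gas1 and Gas6 were 8.04-fold and 7.27-fold lower, Cpxm1 9.69-fold, the proteoglycan gene Lum 6.48-fold, the glutathione transferase gene Gstt1 6.39-fold and the matrix protease gene Mmp3 6.26-fold.

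**Figure D1:**
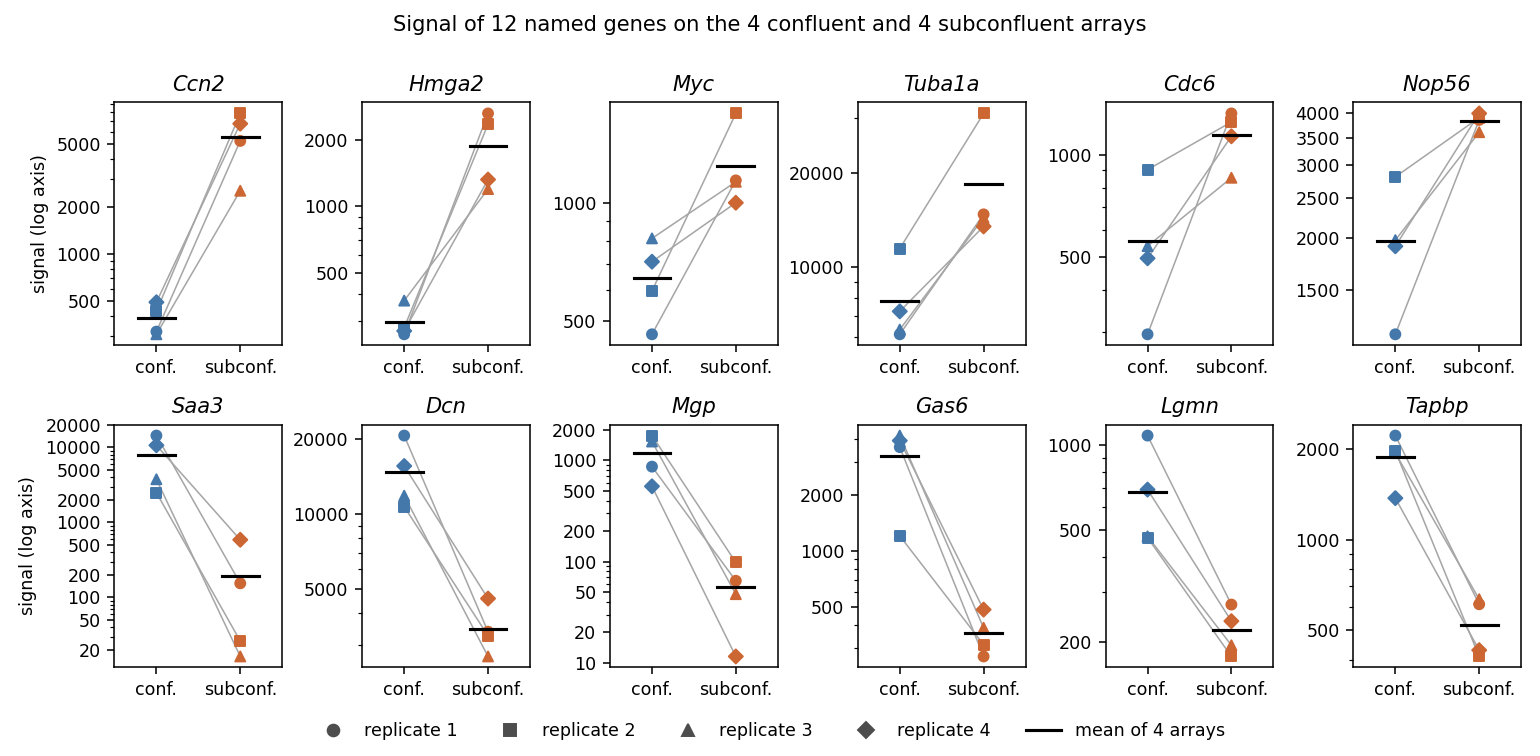
Signal (log axis) of 12 named genes on the 4 confluent and 4 subconfluent arrays, with 1 symbol per replicate number, grey lines joining arrays of the same number and black bars for the mean of 4 arrays. For Ccn2 the means were 388 and 5582, and for Saa3 7816 and 196.

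In all, 165 probe sets were higher and 244 lower in subconfluent cells at a limma adjusted p under 0.05, and of these 51 and 140 differed by at least 1 on the log2 scale. They stood for 132 genes that rose and 205 that fell. With the pairs as a block the counts were 597 higher and 679 lower, and all 409 of the first calls were among them with the same direction. Without pair 1, 3 or 4 the paired counts were 258 and 353, 223 and 367, and 237 and 413, against 652 and 618 without pair 2. In 406 of the 409 the direction was the same in all 4 pairs, and in all 409 it was the same within lot A (1 array against 1) and within lot C (1 against 2). These probe sets were chosen on the same arrays, so such agreement is largely given by the choice. Over all 6007 tested probe sets the shares with the direction of all arrays were 84.1% within lot A, 80.8% within lot C and 42.8% in all 4 pairs. With chip lot as a block 368 were higher and 315 lower, and among the 3 arrays of lot C alone 2 were higher and 3 lower. For Ccn2 the log2 difference was 3.83 within lot A and 3.54 within lot C, and for Saa3 -6.14 and -4.21. The counts of the unpaired fit depended on single arrays, where each fit without 1 array also broke a pair. Without confluent replicates 1 to 4 in turn they were 73 higher and 110 lower, 342 and 345, 43 and 95, and 57 and 103. Without subconfluent replicates 1 to 4 they were 55 and 120, 46 and 93, 90 and 164, and 18 and 80. Of the 24 genes with the largest changes, Snora7a, Slc20a1, Cd44, Plk2, Ccn1, Fubp1, Epha2 and Lum lost their call when single arrays were left out (each array but confluent replicate 2 ended at least 1), with adjusted p up to 0.0778. The other 16 kept it in all 8 fits. Without confluent replicate 1 the fall of Lum was 3.80-fold in place of 6.48-fold, and without subconfluent replicate 4 that of Saa3 was 61.5-fold in place of 38.8-fold.

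Genes of DNA replication, mitosis and the microtubule system were higher as groups in subconfluent cells by camera's preset correlation, though not with an estimated one. Of the DNA replication genes, 4 of 43 members rose (13 adjusted over the list alone, 18 with the pairs as a block) and 0 fell, with a median log2 difference of 0.53 (camera adjusted p = 2.29e-09, and adjusted p = 0.299 with an estimated correlation). Those 4 were Cdc6, which loads the replicative helicase (1.04, adjusted p = 0.0456), the ribonucleotide reductase gene Rrm1 (0.92), the primase gene Prim1 (0.95) and Gmnn (0.80), which encodes geminin, an inhibitor of relicensing. Of the mitotic genes, 2 of 41 members rose, Birc5 (0.99) and Cdc20 (0.92) (23 adjusted over the list alone, 22 with the pairs as a block). The mitotic median was 0.70 (adjusted p = 1.57e-10, and adjusted p = 0.299 with an estimated correlation). Cdk1, the main mitotic kinase, was 0.96 (adjusted p = 0.0532; 0.0128 with the pairs as a block). Among tubulins and microtubule-associated proteins 4 of 29 members rose (4 adjusted over the list alone, 7 with the pairs as a block), namely Tuba1a (1.19), Tubb6 (1.03), Tubb5 (0.84) and Tuba1c (0.81), whose probe sets can also detect related tubulins, and the list's median was 0.16 (adjusted p = 0.0456, and adjusted p = 0.299 with an estimated correlation). Of 11 kinesin motor genes 0 passed limma's test over all probe sets (5 at an unadjusted p under 0.05; 3 adjusted over the list alone, 4 with the pairs as a block), while the list median was 0.54 (adjusted p = 0.00429, and adjusted p = 0.287 with an estimated correlation). Its Kif20a and Kif23, motors of cell division, were 1.03 and 0.74 (limma adjusted p = 0.0667 and 0.0721, or 0.00589 and 0.0148 with the pairs as a block). The probe set of Kif20a can detect related sequences. These 4 lists follow categories named in the labels for the same samples, so they are not independent evidence of direction.

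In the same order, the 4 medians were 0.73, 0.92, 0.10 and 0.90 with chip lot as a block, 1.24, 1.41, 0.44 and 1.29 within lot A and 0.39, 0.59, 0.11 and 0.61 within lot C. The microtubule list lost its call without confluent replicate 1 (camera adjusted p = 0.106), subconfluent replicate 1 (0.0534) or subconfluent replicate 2 (0.0520). It also lost it within lot C, where 1 confluent array stood against 2. Each of the 10 genes that rose in these lists lost its call without some arrays (each array but confluent replicate 2 ended at least 1), with adjusted p up to 0.111, and each passed with the pairs as a block. Without 1 array the counts of members that rose ran from 0 to 16 for DNA replication, 0 to 21 for mitosis, 0 to 4 for microtubules and 0 to 4 for kinesins, highest without confluent replicate 2. Without confluent replicate 1 the medians of DNA replication, mitosis and kinesins were 0.32, 0.42 and 0.34, and that of microtubules was 0.05 without subconfluent replicate 1 and 0.24 without subconfluent replicate 3. By fry, which does not compare with other genes, the shifts of DNA replication and mitosis did not pass (adjusted p = 0.0792 and 0.0681). Relative to the confluent mean, the mitotic list stood at -0.68 on confluent replicate 1 and 0.46 on confluent replicate 2, against 0.63 to 0.70 on the subconfluent arrays. Fibroblast and pericyte markers stood at -1.44 to -1.04 on the same subconfluent arrays.

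**Figure D2:**
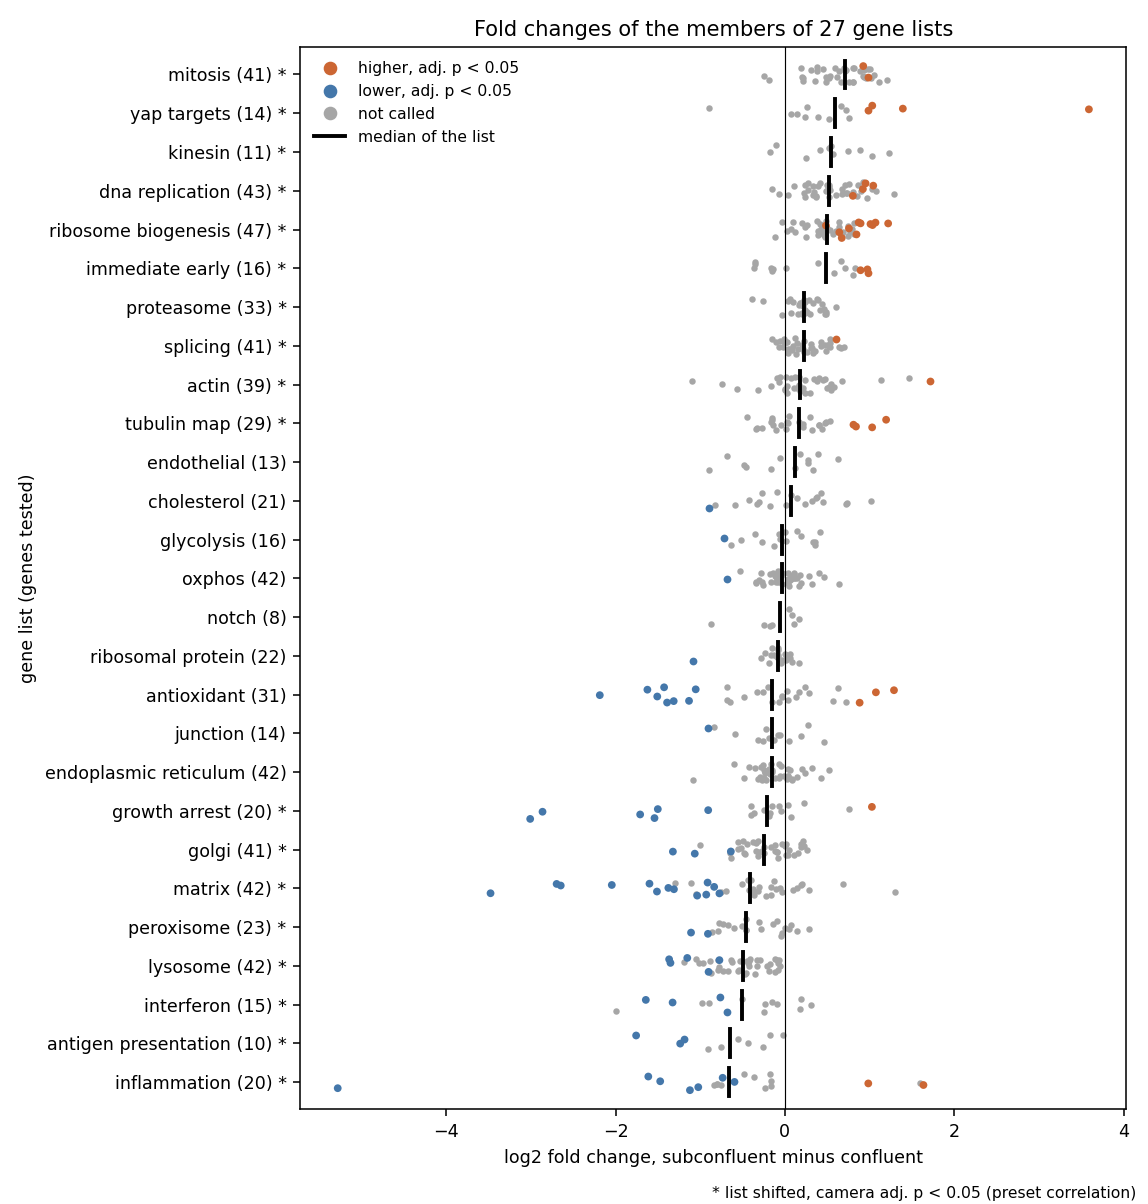
Log2 difference, subconfluent minus confluent, of each tested member of 27 gene lists, with 1 point per gene, orange and blue for genes at limma adjusted p under 0.05 and a black bar for the list median. The medians ran from -0.67 for inflammation to 0.70 for mitosis, and an asterisk marks lists shifted by camera with the preset correlation, which none were with an estimated correlation.

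Genes of ribosome production were higher as a group by camera's preset correlation, though not with an estimated one. In the list of nucleolar and MYC-responsive growth genes 11 of 47 members rose (30 adjusted over the list alone, 29 with the pairs as a block) and 0 fell. The median was 0.50 (camera adjusted p = 5.44e-13, and adjusted p = 0.287 with an estimated correlation). Examples were Mybbp1a, an rRNA transcription regulator, at 1.22 ± 0.23 (SE, adjusted p = 0.0160), the ribosome assembly genes Bop1 (1.07) and Ebna1bp2 (1.03), and Nop56 (1.01), part of the complex that methylates rRNA. Myc, a transcription factor that drives growth genes, rose by 0.89 (adjusted p = 0.0324). The cytosolic ribosomal proteins themselves had a median of -0.08 (adjusted p = 0.248; 0.0374 with chip lot as a block, where the median was -0.17, against -0.29 within lot A and -0.13 within lot C; 0.0208 without subconfluent replicate 2), and 1 of 22 members fell, Rpl22 (-1.08, adjusted p = 0.0136; 1 adjusted over the list alone). The splicing list had a median of 0.22 (adjusted p = 0.000593, and adjusted p = 0.287 with an estimated correlation), with Sf3a3 (0.60) the 1 of 41 members that rose (0 adjusted over the list alone, 8 with the pairs as a block). For the proteasome list the median was 0.23 (adjusted p = 0.00114, and adjusted p = 0.299 with an estimated correlation), with 0 of 33 members past limma's threshold (10 at an unadjusted p under 0.05; 0 adjusted over the list alone, 5 with the pairs as a block, where 1 fell), Psmd1 being the member with the smallest p (0.61, adjusted p = 0.0590). For growth genes, splicing and proteasome the medians were 0.64, 0.32 and 0.37 with chip lot as a block, 0.86, 0.45 and 0.51 within lot A and 0.47, 0.24 and 0.30 within lot C. When single arrays were left out, Bop1, Nop56, Myc and Sf3a3 lost their calls (each array but confluent replicate 2 ended at least 1), with adjusted p up to 0.109, and Mybbp1a and Ebna1bp2 did not. The counts that rose then ran from 2 to 18 for growth genes and 0 to 3 for splicing, highest without confluent replicate 2. The splicing median was 0.14 without confluent replicate 1. Relative to the confluent mean the growth genes stood at -0.32 on confluent replicate 1, 0.26 on confluent replicate 2 and 0.47 to 0.64 on the subconfluent arrays, where fibroblast and pericyte markers stood at -1.44 to -1.04.

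Targets of YAP and TEAD, the transcription regulators that respond to cell density and tension, were higher by camera's preset correlation, though not with an estimated one. In that list 4 of 14 members rose (8 adjusted over the list alone, 7 with the pairs as a block), Ccn2, Ccn1, the tissue factor gene F3 (1.03, adjusted p = 0.0424) and Birc5, and 0 fell (1 adjusted over the list alone). The median was 0.59 (camera adjusted p = 0.000188, and adjusted p = 0.287 with an estimated correlation). Not all members moved this way. Edn1 was -0.89 (limma adjusted p = 0.133), and Lats2 and Amotl2 were 0.08 and 0.14 (0.838 and 0.718), named here after their values were seen. Immediate early genes had a median of 0.49 (camera adjusted p = 0.0152, and adjusted p = 0.299 with an estimated correlation), and 3 of 16 members rose (6 adjusted over the list alone, 8 with the pairs as a block), the transcription factor genes Fosl1 (0.97) and Myc and the phosphatase gene Dusp6 (0.99). Its members Egr1, Dusp1, Btg2, Jund, Fosb and Zfp36 had negative differences that did not pass. Fos and Jun lay under the signal minimum, and all of these were named beyond the rule. The actin and focal adhesion list had a median of 0.18 (adjusted p = 0.0107, and adjusted p = 0.316 with an estimated correlation), and 1 of 39 members rose, Pdlim1 (1.72, adjusted p = 0.0307; 1 adjusted over the list alone, 8 with the pairs as a block, where 2 fell). The smooth muscle type members Acta2 and Tagln stood at 1.14 and 1.47 (adjusted p = 0.228 and 0.108; 0.0172 and 0.0102 with the pairs as a block). Of the junction genes 1 of 14 members fell, Cd47 (-0.91, adjusted p = 0.0319; 2 adjusted over the list alone, 3 with the pairs as a block, where 1 rose), and the list was not shifted (median -0.15, adjusted p = 0.228; -0.22 with chip lot as a block, -0.20 within lot A and -0.22 within lot C). For YAP targets, immediate early genes and actin the medians were 0.50, 0.16 and 0.07 with chip lot as a block, 0.48, 0.10 and 0.09 within lot A and 0.42, 0.29 and 0.11 within lot C. With the lot as a block immediate early genes (camera adjusted p = 0.221) and actin (0.199) were no longer called. Actin also lost its call within lot C, where 1 confluent array stood against 2. The immediate early call ended without confluent replicate 2 (0.138, median 0.31) and the actin call without subconfluent replicate 2 (0.120, median 0.09). By fry neither list passed (adjusted p = 0.123 for both). Single left-out arrays (each of the 8 arrays ended at least 1) ended the calls of Ccn1, F3, Birc5, Fosl1, Dusp6, Myc, Pdlim1 and Cd47, with limma adjusted p up to 0.111, and none ended that of Ccn2. The counts that rose then ran from 1 to 4 for YAP targets and from 0 to 2 for immediate early genes and for actin. Relative to the confluent mean, fibroblast and pericyte markers stood at -1.44 to -1.04 on the same subconfluent arrays.

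Lysosomal, peroxisomal and Golgi genes were lower as groups by camera's preset correlation, though not with an estimated one. All 42 lysosomal genes had a negative log2 difference, and 5 of them fell (19 adjusted over the list alone, 25 with the pairs as a block). The list's median was -0.50 (camera adjusted p = 2.29e-09, and adjusted p = 0.287 with an estimated correlation). Those that fell were the protease genes Lgmn (-1.37, adjusted p = 0.0160) and Ctsb (-0.90, named after its value was seen), the glycosidase genes Naglu (-1.35) and Glb1 (-1.15), and Scarb2 (-0.77), a membrane protein. Of the Golgi genes 3 of 41 members fell (5 adjusted over the list alone, 9 with the pairs as a block), the vesicle fusion gene Stx5a (-1.32, adjusted p = 0.0137) and the mannosidase genes Man1a (-1.06) and Man2a1 (-0.64). The Golgi median was -0.25 (adjusted p = 0.00362, and adjusted p = 0.287 with an estimated correlation). Of the peroxisomal genes 2 of 23 members fell (2 adjusted over the list alone, 8 with the pairs as a block), Acaa1a (-1.11) of fatty acid oxidation and Idh1 (-0.91). The peroxisome median was -0.46 (adjusted p = 0.00202, and adjusted p = 0.287 with an estimated correlation). The endoplasmic reticulum list was not shifted (median -0.15, adjusted p = 0.146; 0.0484 without subconfluent replicate 2), and 0 of its 42 members passed limma's threshold (5 at an unadjusted p under 0.05; 0 adjusted over the list alone, and with the pairs as a block 1 higher and 2 lower). Its Xbp1, a transcription factor of protein folding, was -1.08 (adjusted p = 0.0549; 0.00280 with the pairs as a block). The labels name these 4 categories for the same samples, so the lists are not independent evidence of direction. For endoplasmic reticulum, Golgi, lysosome and peroxisome the medians were -0.17, -0.36, -0.55 and -0.47 with chip lot as a block, -0.12, -0.38, -0.83 and -0.51 within lot A and -0.15, -0.33, -0.42 and -0.39 within lot C. Left-out arrays (each array but confluent replicate 2 ended at least 1) ended the calls of Naglu, Glb1, Scarb2, Ctsb, Man1a, Man2a1, Acaa1a and Idh1, with adjusted p up to 0.0998, but not those of Lgmn and Stx5a. The counts that fell then ran from 1 to 15 for lysosome, 1 to 5 for Golgi and 0 to 4 for peroxisome, highest without confluent replicate 2. The peroxisome median was -0.23 without subconfluent replicate 2, and the Golgi median -0.15 without confluent replicate 3. Fibroblast and pericyte markers were also lower as a group, with a median of -1.06. The lysosome list stood lowest within each group on replicate 2, at -0.32 and -0.90 relative to the confluent mean.

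Among cell cycle inhibitors and growth arrest genes 6 of 20 members fell (7 adjusted over the list alone, 6 with the pairs as a block) and 1 rose (2 adjusted over the list alone, 2 with the pairs as a block). Gas1, a membrane protein induced at growth arrest, had a signal of 6629 ± 2099.5 in confluent and 860.2 ± 560.2 in subconfluent cells (SD, n = 4). Mxd4, an antagonist of MYC, fell by 1.71 ± 0.16 on the log2 scale (SE, adjusted p = 0.000555), and Ccng2, a cyclin of arrested cells, by 1.54 (adjusted p = 0.00745). The stress genes Gadd45a (-1.50) and Sesn1 (-0.91) also fell, and Gadd45g (1.03) rose; these 3 were named after their values were seen. The list's median was -0.22 and its mean -0.57 (camera adjusted p = 0.00232; adjusted p = 0.287 with an estimated correlation). Fibroblast and pericyte markers were lower on the same arrays, with means of -1.44 to -1.04 on the subconfluent arrays against -0.66 to -0.53 for growth arrest, relative to the confluent mean, and both lists stood highest on confluent replicate 1 (0.68 and 0.25). The growth arrest median was -0.31 with chip lot as a block, -0.50 within lot A and -0.21 within lot C. Within lot C, where 1 confluent array stood against 2, the call ended although the median stayed near that of all arrays. Gene calls that ended without single arrays (each array but confluent replicate 2 ended at least 1) were those of Gadd45a, Sesn1 and Gadd45g, with adjusted p up to 0.0782.

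Extracellular matrix genes were lower in subconfluent cells. Of the matrix list 13 of 42 members fell (17 adjusted over the list alone, 21 with the pairs as a block) and 0 rose (2 adjusted over the list alone, 2 with the pairs as a block), and the median was -0.42 (camera adjusted p = 6.17e-07; adjusted p = 0.287 with an estimated correlation). The proteoglycan gene Dcn had a signal of 14708 ± 4485 in confluent and 3476 ± 799 in subconfluent cells (SD, n = 4). Besides Mgp, Mmp3 and Lum, the plasminogen activator gene Plat fell by 1.51 on the log2 scale (adjusted p = 0.00629), and the collagen genes Col3a1 and Col1a2 by 1.31 and 1.04. Several of these genes are also markers of fibroblasts and pericytes. In that marker list 5 of 8 members fell (6 adjusted over the list alone, 7 with the pairs as a block), with a median of -1.06. They were Dcn, Lum, Col3a1, Col1a2 and, named after its value was seen, Tcf21 (-0.76, limma adjusted p = 0.0488). Col1a1, named beyond the rule, was -0.39 (limma adjusted p = 0.280, or 0.0221 with the pairs as a block). Of 3 smooth muscle markers tested, Mylk, a myosin light chain kinase, fell (-1.84, adjusted p = 0.0163), and Acta2 and Tagln did not pass the test (with 1 higher adjusted over the list alone and 2 higher with the pairs as a block). For the matrix and the fibroblast and pericyte lists the medians were -0.66 and -1.10 with chip lot as a block, -0.75 and -1.39 within lot A and -0.53 and -0.97 within lot C. The calls of Lum, Col1a2, Col3a1 and Tcf21 ended when single arrays were left out (each of the 8 arrays ended at least 1), with adjusted p up to 0.114, and the count of matrix genes that fell then ran from 5 to 15, highest without confluent replicate 2.

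Genes of immunity and inflammation were lower as groups by camera's preset correlation, though not with an estimated one. In the antigen presentation list all 10 members had a negative log2 difference, and 3 of them fell (6 adjusted over the list alone, 6 with the pairs as a block). The list's median was -0.65 (camera adjusted p = 0.000173, and adjusted p = 0.287 with an estimated correlation). Tapbp, which loads peptides onto class I molecules, fell by 1.76 on the log2 scale (adjusted p = 0.00155), the proteasome activator gene Psme1 by 1.18, and the class I gene H2-K1, whose probe set can detect related class I genes, by 1.24. Of the interferon response genes 4 of 15 members fell (5 adjusted over the list alone, 7 with the pairs as a block), Ifi204 (-1.64), Lgals3bp (-1.33) and the transcription factor genes Irf1 (-0.76) and Irf9 (-0.68). The interferon median was -0.51 (adjusted p = 0.00414, and adjusted p = 0.336 with an estimated correlation). Of the chemokines, cytokines and NF-kappaB targets 7 of 20 members fell (8 adjusted over the list alone, 10 with the pairs as a block), with a median of -0.67 (adjusted p = 0.000888, and adjusted p = 0.287 with an estimated correlation). Besides Saa3 these included the complement genes C1ra (-1.61, adjusted p = 0.009997) and Serping1 (-1.47). In the other direction 2 members rose (3 adjusted over the list alone, 3 with the pairs as a block), Cd44 and the macrophage growth factor gene Csf1 (0.98, adjusted p = 0.00745). For interferon, antigen presentation and inflammation the medians were -0.67, -0.76 and -0.59 with chip lot as a block, -0.80, -0.99 and -0.51 within lot A and -0.44, -0.46 and -0.57 within lot C. Calls ended without single arrays (each array but confluent replicate 2 ended at least 1) for Lgals3bp, Ifi204, Irf1, Irf9, H2-K1, Serping1 and Cd44, with adjusted p up to 0.110. The counts that fell then ran from 0 to 5 for interferon and 2 to 8 for inflammation, highest without confluent replicate 2. The antigen presentation median was -0.43 without confluent replicate 1 and the inflammation median -0.42 without subconfluent replicate 2. The interferon median was -0.78 without confluent replicate 2 and -0.33 without confluent replicate 4, and by fry the interferon list did not pass (adjusted p = 0.0954). Fibroblast and pericyte markers were lower on the same arrays, with a median of -1.06. On subconfluent replicate 2 the interferon list stood lowest, at -1.05 relative to the confluent mean. The 18S rRNA control signal of this array was 2720 at the 3' end against 114 to 548 on the other subconfluent arrays. Its scale factor was also the highest (13.3), and other controls were high on it, such as antisense Gapdh at 4039 against 180 to 1549. The 18S signal at the 3' end alone is thus no measure of its RNA. At the 5' end the 18S signal was 1056 against 11.8 to 34.2 on the other subconfluent arrays. That gap is wider than the gap in scale factors (13.3 against 3.05 to 8.19), and its cause was not tested.

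**Figure D3:**
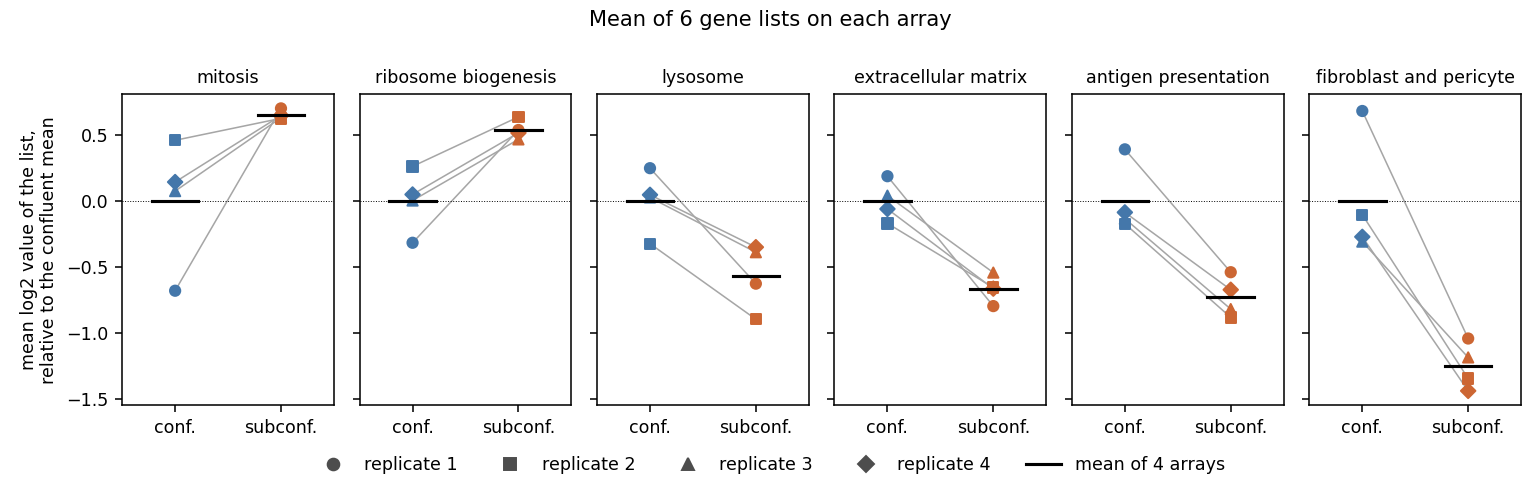
Mean log2 value of 6 gene lists on each array, relative to the mean of the confluent arrays, with 1 symbol per replicate number, grey lines joining arrays of the same number and black bars for group means. The lysosome list lay at -0.90 to -0.35 on the subconfluent arrays and at -0.32 to 0.25 on the confluent arrays.

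Most endothelial markers gave little signal in either group. Of 45 markers on the array 13 reached the mean signal of 200 (28.9%), against 4670 of 8251 genes (56.6%) and 8 of 11 fibroblast and pericyte markers (72.7%). Mean signals over the 8 arrays were 13.0 for Cdh5 (VE-cadherin), 111 for Pecam1, 92.0 for Kdr (a VEGF receptor) and 23.3 for Vwf (von Willebrand factor), which were named after their values were seen. Among the tested markers 0 passed limma's threshold (3 at an unadjusted p under 0.05; 0 adjusted over the list alone), and with the pairs as a block 1 was higher and 2 were lower. These were Procr (0.62, adjusted p = 0.0320 with the block), the adhesion receptor gene Vcam1 (-0.48, 0.0317) and Flt4 (-0.69, 0.0217), Procr being named after its value was seen. The list had a median of 0.12 and a mean of -0.04, and camera gave the direction down (adjusted p = 0.852), so median and test differed in sign. Its median was -0.19 with chip lot as a block, 0.0047 within lot A and -0.17 within lot C. The labels name endothelial genes as a category for these samples, so the list is not independent evidence of direction. Few markers of blood, fat and epithelial cell types passed the signal minimum. They were 2 of 16 macrophage, 3 of 10 lymphocyte, 2 of 7 adipocyte, 2 of 11 epithelial and mesothelial and 0 of 3 red blood cell markers. Of these the lipoprotein lipase gene Lpl, on the adipocyte list, fell (-1.89, adjusted p = 0.00920), and it kept its call in all 8 fits that left out 1 array. Cd14, on the macrophage list, was -0.70 (adjusted p = 0.0563; 0.0228 with the pairs as a block), and Upk3b, on the epithelial and mesothelial list, -0.85 (0.161; 0.0271). The lymphocyte list had a median of -0.07 with 0 members past limma's threshold (0 at an unadjusted p under 0.05).

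Core metabolism and the Notch pathway showed no shift as groups. The cholesterol and fatty acid synthesis list had a median of 0.07 and a mean of 0.05 while camera gave the direction down (adjusted p = 0.852), and 1 of 21 members fell, the desaturase gene Scd1 (-0.90, adjusted p = 0.0179; 1 adjusted over the list alone, 3 with the pairs as a block). Glycolysis had a median of -0.03 (adjusted p = 0.834), with 1 of 16 members lower, Pdk1 (-0.72; 0 adjusted over the list alone, 2 with the pairs as a block, where 1 was higher). The electron transport and ATP synthase list had a median of -0.03 (adjusted p = 0.793), with 1 of 42 members lower, Atp5e (-0.68; 0 adjusted over the list alone, 3 with the pairs as a block, where 1 was higher). Notch pathway genes had a median of -0.05 (adjusted p = 0.626), and 0 of 8 passed limma's threshold (1 at an unadjusted p under 0.05; 0 adjusted over the list alone and 0 with the pairs as a block). In the order cholesterol, glycolysis, electron transport and Notch the medians were 0.15, -0.05, 0.07 and -0.07 with chip lot as a block, 0.79, -0.10, 0.11 and 0.05 within lot A and -0.22, -0.02, -0.01 and -0.17 within lot C. Scd1, Pdk1 and Atp5e lost their calls without single arrays (each array but confluent replicate 2 ended at least 1), with adjusted p up to 0.111.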

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

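The tests of whether a loss of fibroblast-type cells was the only change in their marker genes, of a deviation shared by the samples of experiment 2, and of the share of endothelial markers above the signal minimum were chosen only after the result was seen. Genes of the fibroblast and pericyte list were lower in subconfluent cells by a median of -1.06 on the log2 scale. Chip lot does not account for it, since the median was -1.39 within lot A and -0.97 within lot C, and array brightness does not, since it was -1.06 with the scale factor as a covariate. Fewer such cells, with or without a change in their genes, cannot be told apart from a change within the endothelial cells. The least changed abundant member, Col1a1, was -0.39, short of the bound of -0.5 set for a shared fall, and of 6 members with a mean signal of at least 1000 the intervals (fit with the pairs as a block) excluded the list's median in 3, 1 above it (Col1a1) and 2 below it (Dcn and Lum). Unequal falls do not exclude a loss as the only change, since other cells may express some of these genes, and 0 of the 6 had an interval above 0. The density of the culture, which the design compares, stays open as an untested cause, and 5 of the list's members are also on the matrix list.

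Confluent replicate 2 lay between the groups. On genes called without it, its position between the other confluent arrays (0) and the subconfluent arrays (1) was 0.58 for genes higher and 0.42 for genes lower in subconfluent cells, a difference of 0.161. That is what RNA of subconfluent cells in the sample, or a culture part-way between the states, would give, and both remain candidate explanations. A deviation shared by experiment 2 stays open too. Subconfluent replicate 2 lay at 30.3 on the first principal component, beyond the other subconfluent arrays (13.7 to 15.8), and the lysosome and interferon lists stood lowest in each group on replicate 2. On the scale from the confluent arrays (0) to the other subconfluent arrays (1) it lay at 1.19 for genes lower in subconfluent cells (the others at 0.76 to 0.90) but at 0.95 for genes higher (the others at 0.69 to 0.94), so the test did not decide. Confluent replicate 3, with the next highest scale factor, lay no nearer to the subconfluent arrays than replicate 4 (0.148 and 0.151, a difference of -0.0034). This gave no sign of an effect of array brightness but cannot exclude one. Replicate 2 had the highest scale factor in each group (8.99 and 13.3). Brightness and a deviation shared by experiment 2 therefore cannot be told apart. Confluent replicate 1 lay on the far side of its group, at -0.26 and -0.47.

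Few endothelial markers passed the signal minimum, 28.9% against 56.6% of all genes (Fisher's exact test against the rest, p = 2.18e-04), while the share of fibroblast and pericyte markers was 72.7% (p = 0.369). On the brightest array 15 markers reached 200 and on the dimmest 14. These counts cannot decide on array brightness, since every array was scaled to the same mean. Of all genes 4559 and 4567 reached 200 on these arrays. RNA mostly from cells of another type may lie behind it but cannot be told apart from endothelial cells with a changed state, because no array of fresh endothelial cells is in the series and the fibroblast list holds genes that cultured endothelial cells may also express. Probe sets that give little signal on this array type remain open as well, since the list's median signal of 86.0 cannot be set against RNA in which these genes are known to be expressed.

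The experiment numbers were taken to pair the samples. A split that keeps a pair on 1 side is then not comparable with the real one, so the bound set on all 35 splits into 4 and 4 does not apply. Only 8 splits part all pairs, too few for a share under 0.05. Among them the real split gave 409 called probe sets against a highest other of 0 (7 over all 35, from a split that parts no pair), and with the pairs as a block 1276 against 0. For the number of lists shifted by camera the real split gave 18, and the highest other, confluent replicates 1, 2 and 4 with subconfluent replicate 3 against the rest, also gave 18. That split keeps 3 of 4 arrays of each group together. The 3 splits that part all pairs with 2 arrays of each group on each side, where the group difference cancels, gave 5, 7 and 12 lists (the last with confluent replicates 1 and 3 and subconfluent replicates 2 and 4 on 1 side), with 0 probe sets each. Camera with the preset correlation thus called lists where the difference between the groups cancels.

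In groups of 4, an array was marked when its gap to the nearest other exceeded 0.83 of the group's range, which chance does in about 5% of groups, and 30 of 376 groups (7.98%) had such an array. On confluent replicate 1 the signals, with the range of the other 3 confluent arrays, were 1061 for Plk2 (2936 to 3341), 2195 for Xbp1 (833 to 886), 3018 for Tmed3 (1188 to 1305), 1378 for Cdk1 (3331 to 3408), 6766 for Tubb5 (9826 to 10584), 183 for Kif2c (509.8 to 618), 1113 for Msn (2057 to 2199), 801 for Rpl22 (524 to 551) and 4350.5 for Upk3b (1267 to 1423). On confluent replicate 2 they were 1205 for Gas6 (3606 to 4159.7), 1298 for Pdlim1 (433 to 518) and 634 for Mybbp1a (372 to 400.5). Confluent replicate 3 gave 677 for Otud4 (897 to 941) and 7459.8 for Ldha (9911 to 10478). Confluent replicate 4 gave 16331 for Rps4x (18797 to 18976). Against the other subconfluent arrays, subconfluent replicate 1 gave 155 for Ptprcap (399 to 416) and 968 for Lep (715 to 749). Subconfluent replicate 2 gave 11578 for Plk2 (5896 to 6323), 11.9 for Cpxm1 (118 to 122), 344 for Ech1 (507 to 538), 337 for Prim1 (484 to 506) and 31080.4 for Tuba1a (13518 to 14775). Subconfluent replicate 4 gave 235 for Laptm5 (245 to 245.2). Relative to the confluent mean, the growth arrest list stood at 0.249 and the antigen presentation list at 0.392 on confluent replicate 1 (the others at most -0.08 and -0.09), and the electron transport list at 0.0118 on subconfluent replicate 3 (the others at most -0.02). Among control probe sets, which enter no comparison, the 18S rRNA signal at the 5' end was 445.9 on confluent replicate 2 (7.70 to 73.9 on the others) and 1056 on subconfluent replicate 2 (11.8 to 34.2). On subconfluent replicate 2 the 18S signal at the 3' end was 2720 (114 to 548) and the Actb signal at the 5' end 53775 (25321 to 28040.1). Replicate 2 had the highest scale factor in each group (8.99 and 13.3), which multiplies control signals as well. The scale factors of the other arrays were 3.56 to 7.35 in confluent and 3.05 to 8.19 in subconfluent cells. The 18S signals at the 5' end thus stood much further apart than the scale factors, and the cause was not tested. In 0 of 32 control probe sets did all subconfluent arrays lie above all confluent arrays.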

How the results depend on the processing

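The paired fits without 1 pair were chosen only after the paired result was seen. Signal over background limits what could be seen, since 6007 of 12422 probe sets reached the minimum. The counts of probe sets stayed within 1.5 times the unpaired counts of 165 higher and 244 lower under either other pseudocount, a filter of 500, quantile normalization, median centring, the scale factor as a covariate, no variance trend and genes in place of probe sets. With no filter they fell to 72 and 136, with 12422 probe sets tested in place of 6007, and with a minimum log2 difference of 1 to 51 and 140, which is a stricter rule. With the pairs as a block they were 597 and 679, where the spread between pairs is removed. With chip lot as a random block they were 453 and 485, with chip lot as a fixed block 368 were higher, and with array weights 311 were higher. The fixed block leaves only lots A and C, which held both groups, to inform the difference. Beyond that the cause was not tested. Within lot C, with 3 arrays, they were 2 and 3. Leaving out each array gave 18 to 342 higher and 80 to 345 lower. Each such fit had fewer samples, yet the counts rose to 342 and 345 without confluent replicate 2, and the cause was not tested. Leaving out each pair from the paired fit gave 223 to 652 and 353 to 618. Of the 79 named genes that passed the unpaired fit, 33 passed in all 8 unpaired fits that left out 1 array, 46 did not, and 0 changed sign. Each of these fits broke a pair, so the losses do not show how the paired calls would hold. Calls were lost by 32 of the 79 with no filter and 12 with chip lot as a fixed block. Losses within lot C, with 1 confluent array against 2, are not comparable with these.

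Of the 27 lists 10 were shifted higher and 8 lower. Over all other settings with the preset correlation the counts ran from 8 to 10 and from 7 to 10. With an estimated correlation they were 0 and 0 (lowest adjusted p 0.287), and by fry 6 and 8, or 2 and 7 with the pairs as a block, where the test does not compare with other genes. By fry DNA replication, mitosis, immediate early genes, actin and interferon were not called, and antioxidants were (0.0493). By camera with the preset correlation the block for the pairs changed no list's call, whereas by fry it lowered the number of lists called higher from 6 to 2. The microtubule list also lost its call with array weights (adjusted p = 0.0931), a filter of 500 (0.0596) and the mean of a gene's probe sets (0.0940), growth arrest with a filter of 500 (0.101) and kinesins with no filter (0.225). Antioxidants gained one with array weights (0.0429) and, like the endoplasmic reticulum list, with a filter of 500 (0.0243 and 0.0248).

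Under the alternatives run no called list or named call changed direction, but camera's direction turned for lists that were not called, and the cause was not tested. Over the fits without 1 array the endothelial list's median ran from -0.027 to 0.21, and camera's direction was up without confluent replicate 3 (0.18) and subconfluent replicate 1 (0.18). The cholesterol list turned to up with no filter (0.11), a filter of 500 (0.16), chip lot as a block (0.15) and without confluent replicates 3 and 4 (0.21 and 0.24, within a range of -0.18 to 0.24). Glycolysis turned to up with no filter (-0.031), a filter of 500 (-0.0043), within lot C (-0.022), with array weights (-0.0025) and without confluent replicate 1 (0.059, within -0.038 to 0.059), where some medians kept their sign. For electron transport the direction was up with no filter (-0.032), chip lot as a fixed (0.073) or random block (-0.012), within lot C (-0.0091) and without confluent replicates 2 and 4 (-0.020 and 0.018, within -0.080 to 0.018). Among genes that were not called, Laptm5 was -0.16 within lot C, and Ptprcap was 0.038 without confluent replicate 2 and 0.21 without subconfluent replicate 1 (within -0.23 to 0.21).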

Other observations

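No test was added for these genes after their values were seen. The antioxidant list split into members that rose and members that fell. Of 31 tested genes 3 rose (6 adjusted over the list alone, 6 with the pairs as a block) and 8 fell (12 adjusted over the list alone, 12 with the pairs as a block). Those that rose were the quinone reductase gene Nqo1, from a signal of 146 ± 18.1 in confluent and 432 ± 83.4 in subconfluent cells (SD, n = 4), the thioredoxin reductase gene Txnrd1 (1.07 on the log2 scale) and Gclm (0.88), a subunit of the enzyme that starts glutathione synthesis. Those that fell were the glutathione transferase genes Mgst1 (-2.19, limma adjusted p = 0.0130), Gstm2 (-1.62) and Gstm1 (-1.31, adjusted p = 0.00629), the epoxide hydrolase gene Ephx1 (-1.39), the metallothionein genes Mt2 (-1.51) and Mt1 (-1.13), the retinal dehydrogenase gene Aldh1a1 (-1.43) and the autophagy receptor gene Sqstm1 (-1.05). The transferase probe set of Gstm1 can detect related genes, and the name of that of Nqo1 marks a sequence that may not be unique. Txnrd1, Gclm, Gstm2, Mt1, Mt2, Aldh1a1 and Sqstm1 were named after their values were seen. The list as a whole was not shifted (median -0.15, camera adjusted p = 0.0948; 0.0405 without subconfluent replicate 3), and its median was -0.20 with chip lot as a block, -0.30 within lot A and -0.17 within lot C. The calls of Txnrd1, Gclm, Gstm2, Ephx1, Mt1, Mt2, Aldh1a1 and Sqstm1 ended without single arrays (each array but confluent replicate 2 ended at least 1), with adjusted p up to 0.0924, and those of Nqo1, Mgst1 and Gstm1 did not. The counts then ran from 1 to 4 for members that rose and 3 to 9 for members that fell, highest without confluent replicate 2.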
